A study of Mus musculus with 2 samples.

How the data were processed

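DNase-seq, which cuts accessible DNA with the enzyme DNase I and sequences the cut ends, was run on forebrain tissue of mouse embryos at day 11.5. Per the labels, the tissue came from strain B6NCrl with male and female embryos pooled, and both libraries were sequenced on HiSeq 4000 and NextSeq 500 instruments. The 2 libraries are biological replicates from separate biosamples that share a donor record, and they form 1 group. The labels also say that the record has since been superseded by another one, which was not used here. The aligner, the peak caller and their versions are not given in the sources used here.

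Each library has 3 deposited peak lists, a hotspot list, a footprint list and 2 tracks of cut rate, all on build mm10 and none pooled over replicates. They derive from 2 filtered alignments per library. The deposited peak lists of the second alignment carry a signal, which is tag density normalized to read depth. The strict list was used for all main values; its peaks reach a false discovery rate (FDR) of 0.001 in the deposited cut-rate track, except for 1 of the 131375 peaks of replicate 2, which reaches 0.00185. The longer list goes to an FDR of 0.05. The deposited peak list of the first alignment carries a count of tags in fixed windows of 150 bp. The deposited hotspot lists carry the −log10 of the p-value, given as an FDR. The deposited footprint lists carry a p-value in the form of an FDR threshold of 0.01, and the deposited cut-rate tracks carry a p-value in the form of an FDR per interval. Raw reads and alignments were not analysed here.

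The files give no library totals. The signal of the strict and longer lists moves in steps of fixed size, 0.00382 in replicate 1 and 0.00361 in replicate 2, and 100% of the values below 1 lie within 0.05 tags of a whole number of steps. If a step is 1 tag per 1 M tags, the normalization rests on 261.7 M tags in replicate 1 and 276.7 M tags in replicate 2, a ratio of 1.06. That scale is read from the values and is not stated by the authors. On that scale a strict peak held a median of 221 tags in replicate 1 and 111 in replicate 2. Intervals on shares are 95% Wilson intervals and cover counting error only.

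Some peaks of the strict lists overlap another peak of their own library, 13.3% in replicate 1 and 4.64% in replicate 2. They were kept as deposited for the main values. Merging them left 85536 peaks in replicate 1 and 128181 in replicate 2.

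Genes were the 21827 protein-coding genes of GENCODE M21 on the GRCm38 assembly, and coordinates are counted from 1. A peak within 1 kb of a transcription start site (TSS) of a protein-coding transcript of such a gene was called a promoter peak and any other peak distal, so a distal peak can lie at the start of another transcript or of a noncoding gene. A peak was called shared if it overlapped a peak of the other library by at least 1 bp. Counts of shared distal peaks near a gene are counts of replicate 1 peaks, so they can exceed the number of distal peaks in replicate 2. The overlap from peaks shuffled within chromosomes, 10 times, served as background. Rank agreement was measured across shared peaks, which are not independent replicates, without a p-value.

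The lists tested were 18 sets of genes, of which 359 genes were matched to the annotation and 1, Ahsp, was not. For promoters, the share of members with a promoter peak was compared with 10000 random lists of the same size, drawn from genes in the same decile of promoter CpG ratio. For distal peaks, the mean number within 100 kb of the TSS was compared with 10000 random lists matched on the quintile of gene density. The share of those distal peaks found in 1 library was tested likewise. These permutation tests were two-sided, with Benjamini-Hochberg adjustment over the 18 lists in each library, and a list was called only if the adjusted p was under 0.05 in the same direction in both libraries. The smallest p that the random lists can give is 0.0002.

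Matches to 48 consensus sequences were counted in footprints and in control intervals of equal width from the same library's peaks, outside footprints. They were also counted in the central 150 bp of distal and promoter peaks. A motif was called only if its odds ratio was over 1.2, or under the inverse of that, with an adjusted Fisher exact p under 0.05, in both libraries. A correction of 0.5 was added to each count for the odds ratio. Footprints and peaks are not replicates, so these p-values cover counting within a library. A consensus match does not say which protein is bound.

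The gene lists, consensus sequences, tests, thresholds, alternatives other than those named as added and the rule for named genes were fixed before the data were examined. The rule named the 8 forebrain patterning genes with the most shared distal peaks, the 2 members with the most and the 2 with the fewest in every other list, the 10 genes with the most of all genes, the 10 strongest shared distal peaks by mean rank, and the 3 strongest distal peaks found in 1 library. Alternatives covered the longer list, the 46206 strongest peaks of each library, other promoter and window sizes, unmatched random lists, other controls for motifs and each replicate alone. Merged peaks, the fixed windows of the first alignment, 1 gene per 200 kb locus, shared peaks only, the strict list against the other library's longer list, mirror-image controls and the starts of all transcripts of protein-coding genes were added after seeing the data. No paired analysis was possible because there is 1 group, and no test between groups was made for the same reason.

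In simulated lists of random genes, scored on the deposited peaks, 0% of 360 unchanged lists were called in each of the 3 kinds of list test. These lists were drawn in the same way as the matched random lists, so few calls follow from the design. Their members were drawn singly, so the check does not cover clustered lists such as posterior Hox. Lists given 2 times as many distal peaks were called in 28.3% of 120 cases, and lists given 4 times as many in 97.5%. Lists in which members lost promoter peaks at a rate of 0.5 were called in 70.8%, and lists with 1.5 times the share of peaks found in 1 library in 20%. Interval overlaps were checked against a brute-force count with 0 differences in 2000 intervals. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.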

Results

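DNase I accessibility was mapped in embryonic mouse forebrain, the part of the neural tube that gives rise to the cerebral cortex, basal ganglia and diencephalon, at day 11.5. There was 1 group with 2 biological replicates. The strict peak list held 92412 peaks in replicate 1 and 131375 in replicate 2, a ratio of 1.42. Peak widths summed to 26.7 and 27.3 Mb, with bases in overlapping peaks counted more than once. The footprint lists held 487679 and 474874 short protected intervals. Read as tags per 1 M tags, a scale inferred from the values, the deposited signal implies that the libraries rest on 261.7 M and 276.7 M tags.

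The first comparison asked how far the accessible sites of both replicates coincide. The strongest sites did so almost completely. Of the decile of peaks with the highest signal, 99.7% in replicate 1 and 99.2% in replicate 2 overlapped a peak of the other library, against 7.48% and 0.944% of the weakest decile. Promoter peaks were shared at 80.5% and 85.8%, and distal peaks at 53.9% and 34.0%. Over all peaks the share was 62.1% in replicate 1 (Wilson interval 61.8 to 62.4) and 44.7% in replicate 2 (44.5 to 45.0), against 2.32% and 1.67% for shuffled peaks. Peaks found in 1 library were weak, with medians of 114 and 45.0 tags against 363 and 387 tags for shared peaks. Across the 57384 shared peaks of replicate 1, which are not independent replicates, signal ranks correlated at Spearman rho 0.919, with 0.945 at promoters and 0.878 at distal peaks. The Pearson correlation of log2 signal was 0.926, and 93.1% of shared peaks lay within 2-fold. With the 46206 strongest peaks of each library, the mean share rose from 53.4% to 86.3%.

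**Figure D1:**
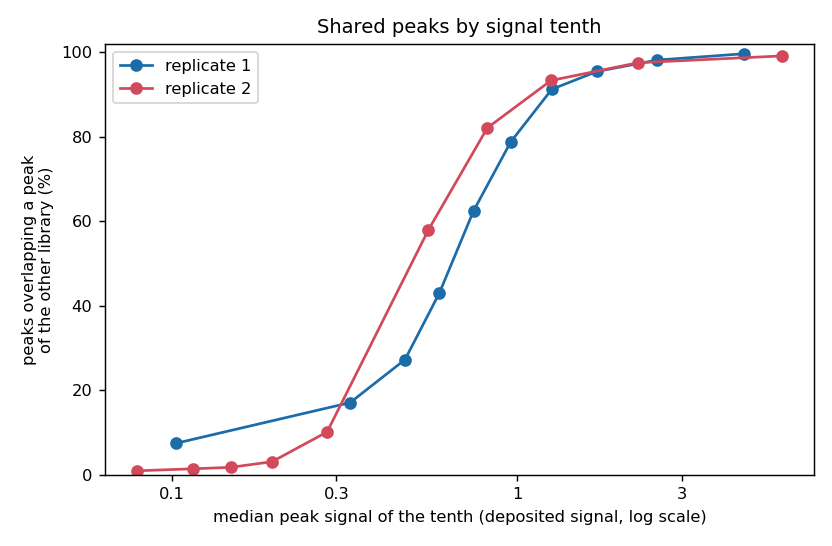
Percent of peaks that overlap a peak of the other library (vertical axis) by decile of peak signal (horizontal axis, median deposited signal, log scale), with 1 line per replicate. The strongest decile is shared at 99.7% and 99.2% and the weakest at 7.48% and 0.944%.

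By mean rank, the strongest shared distal peak lay between genes on chromosome 1, at 195241541 to 195241820 in replicate 1, with signals of 27.0 and 32.6. Its nearest protein-coding TSS is that of Cr2, a complement receptor gene, 64825 bp away, and the small RNA gene Gm27940 starts 534 bp from it. The next lay in an exon of Lars2, the mitochondrial leucyl-tRNA synthetase gene, on chromosome 9 at 123461981 to 123462060, with signals of 23.2 and 25.7. Others among the 10 strongest lay nearest to the TSS of Cd209a, Zfp395, Pak3, Kpna1, Dtnbp1, C87436 and Tex44. The peak assigned to Dtnbp1 lies in an intron of Jarid2, a Polycomb cofactor gene. No filter against regions of artefactual high signal was applied, so whether these peaks are regulatory elements was not tested. Of the strongest peaks found in 1 library and over 1 kb from the TSS of a protein-coding transcript, several lay at other gene starts. In replicate 1 they included a peak 86 bp from the annotated 5' end of Tmpo, a nuclear lamina gene, and one 59 bp from the start of the lincRNA gene C030034I22Rik, with signals of 5.14 and 4.38. In replicate 2, one with a signal of 5.0 covered the 5' end of Hoxa7, 3010 bp from the TSS of its coding transcript. The others there lay 33637 bp from Foxk1 and 7123 bp from the lincRNA gene C430042M11Rik, with signals of 5.78 and 5.33.

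Promoters were the most enriched class of site. They held 30.9% of peaks in replicate 1 and 20.8% in replicate 2 (mean 25.9% ± 7.18, SD, n = 2), against 2.43% of random positions. Introns held 34.3% ± 4.34 against 42.2%, intergenic DNA 31.6% ± 2.37 against 50.8%, and exons 8.28% ± 0.465 against 4.55%. The number of promoter peaks was similar, 28601 and 27319, while intronic peaks numbered 28826 and 49044. Median signal was 1.68 and 1.93 at promoters, against 0.638 and 0.217 in introns. A promoter peak was found in replicate 1 for 14487 protein-coding genes (66.4%) and in replicate 2 for 14412 (66.0%), and 14098 genes had it in both. Among the strongest 46206 peaks of each library the promoter share was 47.4%. Of distal peaks, 7.70% and 5.55% lay within 1 kb of the start of a gene of any type.

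The next comparison asked which gene groups had open promoters more or less often than genes of like promoter CpG content. Genes of mesenchyme and neural crest were higher, with a promoter peak at 23 of 23 members in replicate 1 and 22 of 23 in replicate 2, or 100% and 95.7% against 78.3% in matched lists (adjusted permutation p = 0.0018 and 0.0108). They include Col1a1, a fibrillar collagen gene, with promoter signals of 3.32 and 4.24, and Tfap2a, a regulator of neural crest, with 2.12 and 2.50. Pluripotency and germline genes were lower, with 8 and 10 of 18 members, or 44.4% and 55.6% against 83.3% (adjusted permutation p = 0.0018 and 0.0264). Nanog, a core pluripotency factor, had no promoter peak in either library. Both calls ended when promoters were narrowed to 500 bp. The call of pluripotency and germline genes also ended with the longer peak list, with promoters of 2 kb, with fixed windows and with unmatched random lists, and that of mesenchyme and neural crest genes with the strongest peaks.

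The other 16 lists were not called. Forebrain patterning genes had a promoter peak at 26 and 25 of 26 members, and neural progenitor genes at 20 and 20 of 20. Midbrain, hindbrain and spinal cord genes had one at 20 and 18 of 20. These shares were near the matched medians of 95 to 100%. The matched ranges of these lists ran up to 100%, so none could be called higher whatever the data. That holds for signalling centre, posterior Hox and housekeeping genes too. Nkx2-1, a regulator of ventral forebrain, was the forebrain member without a promoter peak in replicate 2; it was named after its values were seen. Early neuron genes had one at 26 and 27 of 28, signalling centre genes at 20 and 20 of 22, mature neuron genes at 20 and 19 of 20, and housekeeping genes at 25 and 25 of 25. Posterior Hox genes, which pattern the trunk and limbs, had one at 15 and 13 of 19, or 78.9% and 68.4% against 94.7%, with adjusted permutation p of 0.0583 and 0.0072. Among markers of other cells that dissected tissue can hold, macrophage and immune genes had a promoter peak at 0 and 1 of 17 members, or 0% and 5.88% against 23.5% in matched lists. Erythroid genes had one at 4 and 7 of 16, or 25% and 43.8% against 18.8%, endothelial genes at 11 and 10 of 17, or 64.7% and 58.8% against 64.7%, and surface ectoderm and epithelium genes at 13 and 12 of 16, or 81.2% and 75% against 75%. Heart genes had one at 12 and 9 of 18, or 66.7% and 50% against 44.4%, liver genes at 7 and 8 of 20, or 35% and 40% against 50%, skeletal muscle genes at 5 and 7 of 16, or 31.2% and 43.8% against 50%, and mature glia genes at 11 and 10 of 18, or 61.1% and 55.6% against 55.6%.

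Distal peaks were dense around the genes of 10 of the 18 lists, forebrain patterning among them. Forebrain patterning genes had a mean of 42.5 distal peaks within 100 kb in replicate 1 and 35.9 in replicate 2, against 6.08 and 9.85 in lists matched on gene density, a fold of 7.0 and 3.64 (adjusted permutation p = 0.00045 and 0.0009, the p before adjustment being the smallest the random lists can give). All 26 members had more shared distal peaks than the median of 3 over all genes, and 21 of 26 had at least 10, which 12.4% of all genes had. Six3, needed for the anterior forebrain and eye field, had 48 shared distal peaks, counted among the peaks of replicate 1, the most of the list. Next came Zic1 with 39, Nr2f2 with 38, Pax6, a regulator of cortical progenitors, with 35, Barhl2 with 29, Dlx2 with 27, Emx2, which patterns the cortex, with 26, and Dlx1 with 24. Part of this density is overlap of peaks within a library. After merging, chosen after seeing the data, these 8 stood in another order, with Six3 at 36 shared distal peaks, Nr2f2 and Barhl2 at 29 each, Zic1 27, Pax6 26, Dlx2 24 and Emx2 and Dlx1 21 each, and the fold for the list was 6.30 and 3.55.

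Six3 (ENSMUSG00000038805.10) lies on chromosome 17 at 85613608 to 85629302 on the plus strand, with promoter signals of 1.98 and 1.51. Within 100 kb of its TSS lay 100 distal peaks in replicate 1 and 115 in replicate 2. Counts differed more at other loci. Emx2 had 113 and 48, Nr2f2 103 and 44, and Barhl2 42 and 72.

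**Figure D2:**
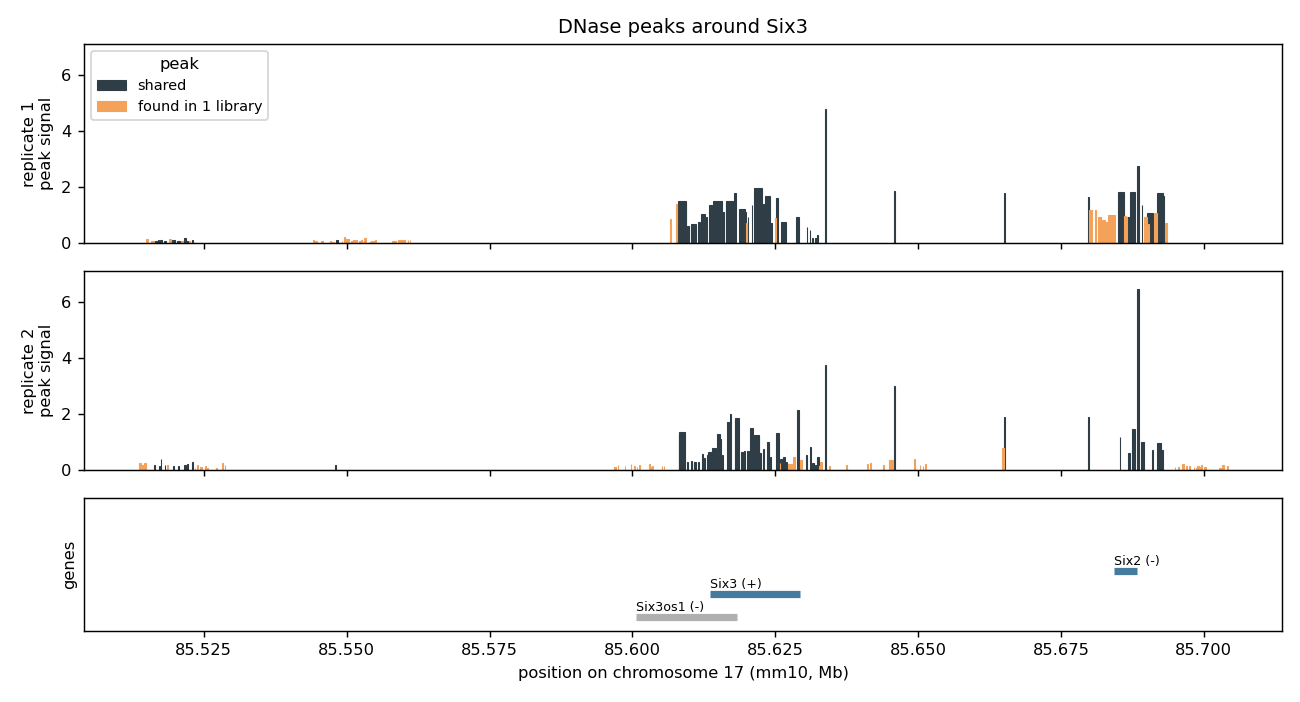
Peaks around Six3 on chromosome 17, with deposited peak signal on the vertical axis and position (mm10, Mb) on the horizontal axis, for replicate 1 (top) and replicate 2 (middle), above protein-coding genes and the transcript Six3os1 (bottom). Dark bars are the shared peaks, of which 48 are distal and within 100 kb of the Six3 start in replicate 1, and orange bars are peaks found in 1 library.

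In all, 10 of the 18 lists were called higher in both libraries and 0 lower; at an unadjusted p under 0.05, 10 lists passed in each library. Among the other 9, posterior Hox genes had means of 82.7 and 75.1 against 10.2 and 17.4, at a fold of 8.10 and 4.32, and their 19 members share 4 loci. Midbrain, hindbrain and spinal cord genes had a fold of 4.90 and 3.12, neural progenitor genes 3.53 and 2.86, signalling centre genes 2.78 and 2.58, and mesenchyme and neural crest genes 2.97 and 1.91. Heart genes followed with 2.85 and 1.88, early neuron genes with 2.47 and 1.73, mature glia genes with 1.84 and 2.10, and skeletal muscle genes with 1.96 and 1.96. The adjusted permutation p of the 10 lists ranged up to 0.0349 in replicate 1 and 0.0454 in replicate 2. With a window of 200 kb the calls of mesenchyme and neural crest, heart, skeletal muscle and mature glia ended, and with unmatched random lists those 4 and early neuron. With 1 gene per 200 kb locus early neuron, skeletal muscle and mature glia were lost, with merged peaks early neuron (adjusted permutation p = 0.0511 in replicate 2), with the strongest peaks heart and with fixed windows skeletal muscle. Whether lists differ from each other was not tested.

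Members of these lists differed widely. Sox1, which marks neural progenitors, had 31 shared distal peaks and Pou3f3 26, while Prom1 had 0 and Fabp7 4. Among early neuron genes, Lhx5 had 33 and Neurod2 21, while Isl1 had 0 and Elavl4 1. Lbx1 and Pax2, of hindbrain and spinal cord, had 39 and 31, and Phox2a had 4. Shh and Wnt1, secreted signals of the ventral and dorsal neural tube, had 26 and 21, and Dkk1 and Rspo2 had 2 each. Hoxd10 and Hoxd11 had 56 each, Hoxb13 15 and Hoxc10 18. Tfap2a had 27 and Col1a1 19, against 0 at Col3a1 and 1 at Dcn. Hand2 and Nkx2-5, regulators of heart, had 37 and 22, whereas Actn2, a gene of the contractile apparatus, and Ryr2, a calcium channel gene, had 0 each. Pax3 had 24 and Ckm 16, against 0 at Neb and 1 at Actn3. Olig2 had 21 and Gfap 20, against 3 at Aqp4.

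The 8 lists without a call held markers of blood, vessels, immune cells, epithelium, liver, pluripotency and mature neurons, and housekeeping genes. Erythroid genes had a fold of 1.13 and 0.929, macrophage and immune genes 1.13 and 1.38, endothelial genes 1.39 and 1.37, and surface ectoderm and epithelium genes 1.57 and 1.49. Liver genes had 1.63 and 1.19, pluripotency and germline genes 1.2 and 1.23, mature neuron genes 1.11 and 0.947, and housekeeping genes 1.28 and 1.48. In simulated lists a 2-fold excess was called in 28.3% of cases, so a fold of this size was often not detectable. Single members still had many shared distal peaks. Nfe2 had 30 and Klf1 18, Egfl7 14 and Sox18 12, Cd4 13 and Tyrobp 13, Wnt6 22 and Krt18 16, Onecut1 22 and Foxa3 18, Fgf4 14 and Nanog 14, Slc17a7 19 and Slc32a1 16, and Actb 30. Members with the fewest, at 0 or 1 each, included Hbb-bs, Emcn, Kdr, Cd8a, Itgam, Trp63, Krt5, Serpina1a, Cyp7a1, Nr0b1, Tfcp2l1, Pgk1 and Reep5.

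**Figure D3:**
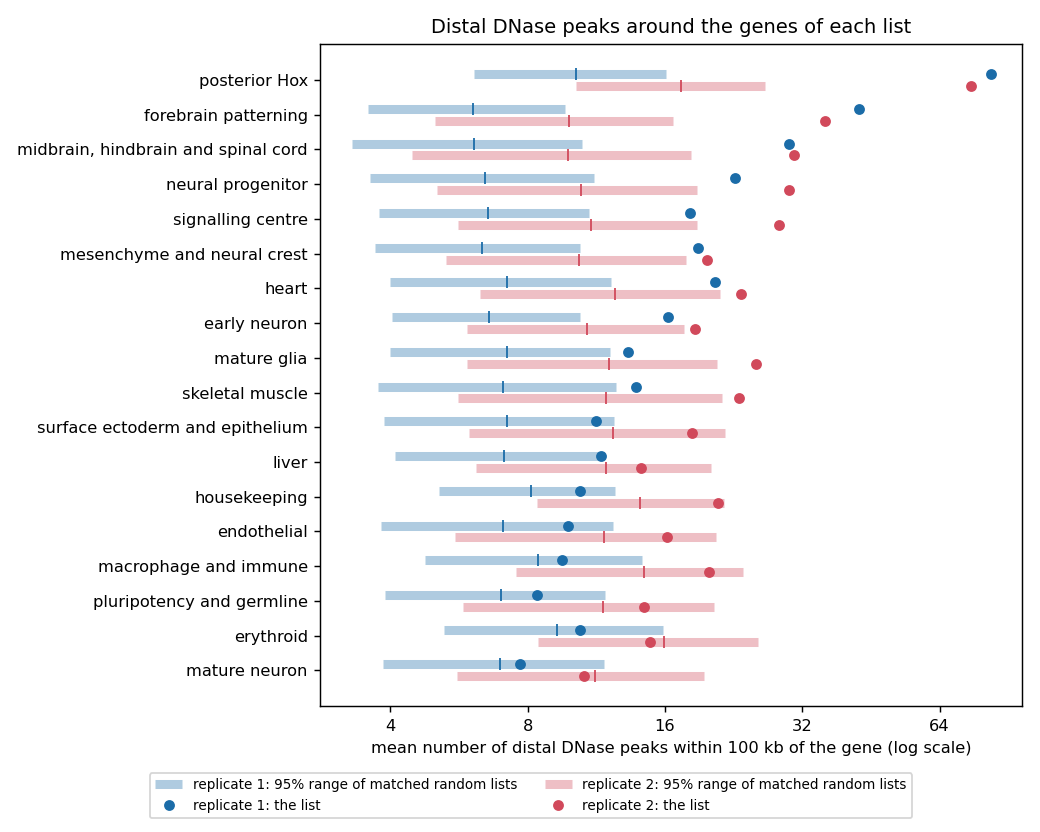
Mean number of distal peaks within 100 kb of the genes of each list (horizontal axis, log scale; points) for replicate 1 (blue) and replicate 2 (red), over the median (tick) and 95% range (bar) of 10000 matched random lists. The forebrain patterning list lies at 42.5 and 35.9, against medians of 6.08 and 9.85.

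Over all protein-coding genes, any gene with a TSS within 100 kb of one already named was skipped. The most shared distal peaks lay around Evx2, at the end of the HoxD cluster, with 56, and Hoxa10 with 55. Those that followed included Polg with 52, Btn2a2 and Six3 with 48 each, Mef2d with 45, Hoxd1 with 44, Celf5 with 42 and Rhbg with 41. This order depends on overlapping peaks. After merging, Btn2a2 kept 48, while Evx2 had 47, Polg 42, Hoxa10 and Celf5 39 each, Hoxd1 37, Six3 36, Mef2d 34 and Rhbg 31. The windows reach 100 kb to each side. Those of Evx2 and Hoxd1, and of Mef2d and Rhbg, therefore overlap and can count the same peaks.

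Distal peaks found in 1 library were then compared between gene lists, to ask whether the libraries differ around markers of other tissues. Of the 18 lists 0 were called. The rule asks for the same direction in both libraries, so it cannot call a list whose sites are open in 1 library only. Such a list would go up in that library and down in the other. Without that rule, 0 lists passed an adjusted permutation p of 0.05 in either library. At an unadjusted p under 0.05 only 1 list passed in replicate 1 and 2 in replicate 2. The lowest adjusted permutation p was 0.554 and 0.299. Around forebrain patterning genes, 53.3% of distal peaks of replicate 1 were found in that library alone, against 45.6% in matched lists, and 40.6% of those of replicate 2, against 65.4% (permutation p = 0.0328 before adjustment). Posterior Hox genes had 51.7% against 38.6% and 44.0% against 62.5%, and housekeeping genes 26.9% against 39.7% and 62.7% against 63.9%. In simulated lists, 1.5 times the share in both libraries was called in 20% of cases, so differences of that size were mostly not detectable.

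Footprints, the short intervals protected from DNase I inside accessible DNA, were compared with control intervals to ask which factor families leave them. Motifs of CTCF, which organizes chromatin loops, had an odds ratio of 122 in replicate 1 (95% interval 91.4 to 163) and 107 in replicate 2 (81.1 to 142). REST, a repressor of neuronal genes outside neurons, had 541 (33.8 to 8676), from 270 matches against 0 in controls, and 43.6 (18.7 to 101). NRF1 had 46.8 and 51.2, RFX 26.7 and 15.6, ZBTB33 13.6 and 23.6, YY1 13.7 and 9.31 and the NFI palindrome 12.3 and 20.7. CRE had 11.7 and 10.6, SP/KLF 11 and 12.8 and ZIC 9.77 and 8.55. With controls matched on GC, SP/KLF fell to 3.91 and 3.07, YY1 to 8.05 and 6.4 and ZIC to 7.43 and 5.4, and NFI had 20.6 and 6.31. ETS had 5.60 and 3.27, TFAP2 2.10 and 2.28, and GLI, the effector family of Shh signalling, 1.93 and 3.02. Most of these odds ratios fell with mirror-image controls, CTCF to 70.8 and 49.5, NRF1 to 22.8 and 14.1, ZBTB33 to 4.23 and 5.67, YY1 to 5.06 and 3.04, CRE to 8.34 and 6.28, SP/KLF to 10.2 and 8.26, ZIC to 4.18 and 4.45 and ETS to 3.17 and 1.34. NFI had 15.0 and 3.67. REST then rested on 33 and 40 matches against 1 and 0 in controls (95% intervals of the odds ratio 4.35 to 115 and 4.98 to 1318), and RFX on 38 and 20 against 0 and 0 (4.73 to 1254 and 2.48 to 678). The call of TFAP2 ended with GC-matched controls, at 1.03 and 1.0, and that of GLI with mirror-image controls, at 1.79 and 1.53. GC was matched on the interval itself, motif bases included, so that matching can take away part of a true difference. Of ZIC matches in footprints, 49.1% and 49.6% lay on a CTCF match. Of all CTCF matches in peaks, 96.6% and 94.2% lay in a footprint, as did 97.6% and 91.7% of REST matches, against 8.87% and 6.74% of homeodomain matches.

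In all, 16 of 48 motifs were higher and 16 lower in footprints in both libraries. The lower group held the homeodomain motif TAATTA, at 0.515 and 0.471, FOX at 0.212 and 0.311, MEIS at 0.495 and 0.552, OTX at 0.574 and 0.529, GATA at 0.576 and 0.509 and AP-1 at 0.447 and 0.566. Footprints were richer in G and C than controls, with 64.3% and 63.8% against 55.8% and 54.6%. With controls matched on GC, 5 motifs were lower in place of 16. As the GC matched includes the bases of the motif, lost calls do not show that base composition was the cause. The calls of homeodomain, at 1.11 and 1.25, OTX, at 1.00 and 0.931, and GATA, at 0.923 and 0.959, were among those that ended, while FOX stayed lower at 0.430 and 0.625, MEIS at 0.639 and 0.716 and AP-1 at 0.653 and 0.762. SOX, which was not called at first, was then higher at 1.66 and 1.51. In shared peaks, 54.3% and 63.5% of footprints overlapped one of the other library, against 15.1% and 21.6% of control intervals. Control intervals lie outside the footprints of their own library, so where the libraries agree they meet fewer footprints of the other. This gap is therefore partly built in. Of all footprints, 38.1% and 39.9% overlapped one of the other library. Only 65.2% and 64.2% of footprints overlapped a strict peak of their library, while all controls were drawn from those peaks. With only those footprints kept, 34 motifs were called, 18 higher and 16 lower. E-box CACGTG and NFY were gained and none were lost.

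**Figure D4:**
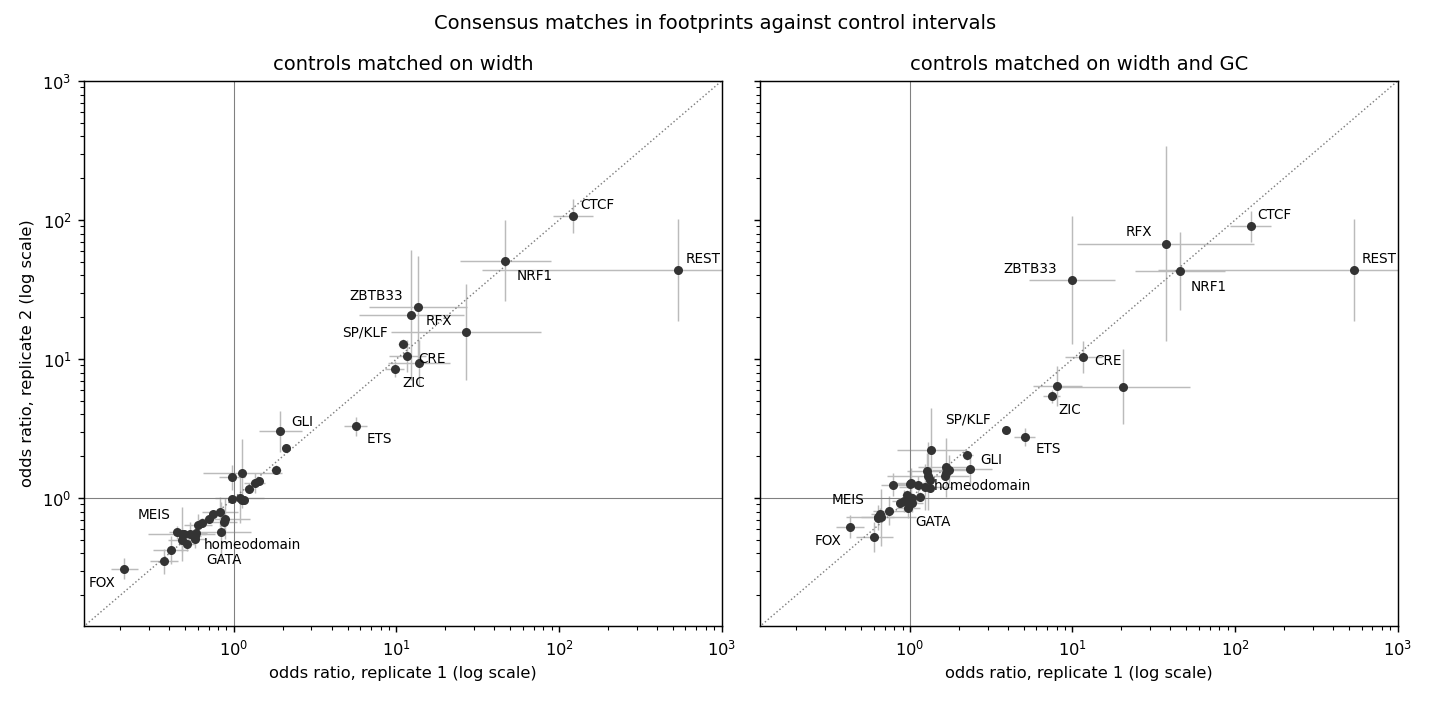
Odds ratios of consensus matches in footprints against control intervals, replicate 1 (horizontal axis) against replicate 2 (vertical axis), both on log scales, with 95% intervals, for motifs with at least 20 matches in footprints; the interval of REST in replicate 1 runs past the axis to 8676. CTCF lies at 122 and 107, and homeodomain moves from 0.515 and 0.471 with width-matched controls (left) to 1.11 and 1.25 with GC-matched controls (right).

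The last comparison asked which motifs separate distal from promoter peaks. Motifs of homeodomain and SOX factors and the E-box of proneural factors were among those more frequent at distal peaks. The homeodomain motif had odds ratios of 3.42 (95% interval 2.97 to 3.93) and 4.03 (3.45 to 4.71), LHX 3.32 and 4.52, PBX-HOX 3.01 and 3.55, OTX 1.74 and 2.28, SOX 1.93 and 1.78, TCF/LEF 2.33 and 2.21 and the E-box of proneural factors 2.41 and 2.71. CTCF was also distal, at 9.41 and 4.86. So were RUNX at 2.28 and 2.82, GATA at 1.88 and 2.35, TEAD at 1.94 and 2.00 and AP-1 at 1.79 and 2.03. Distal and promoter peaks were not matched on base composition, so its part in these odds ratios was not tested. Promoter peaks were richer in ETS, at 0.111 and 0.0810, NRF1 at 0.104 and 0.0703, YY1 at 0.0425 and 0.0408, ZBTB33 at 0.0157 and 0.0074, CRE at 0.205 and 0.139, SP/KLF at 0.201 and 0.129, NFY at 0.544 and 0.456 and the E-box CACGTG at 0.672 and 0.604. In all, 24 of 48 motifs were higher at distal peaks and 11 lower in both libraries. With the whole peak in place of its central 150 bp, the count fell from 35 to 23, and the calls of OTX, SOX, MEIS, FOX and ZIC were among those that ended.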

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

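The alternatives with merged peaks, the fixed windows of the first alignment, 1 gene per locus, shared peaks only, the other library's longer list, mirror-image controls and the starts of all transcripts of protein-coding genes were chosen after seeing the data; where a value changed, the cause was not tested unless stated. Of 63 main values under alternatives, 45 stayed within the bounds and 18 moved. The mean share of shared peaks, 53.4%, moved to 86.3% with the strongest peaks and to 37.6% with 50% reciprocal overlap, which by construction counts fewer pairs. Spearman rho, 0.919, was 0.925 with the longer list, 0.891 with the strongest peaks, 0.935 with reciprocal overlap, 0.926 with fixed windows and 0.924 with merged peaks. The promoter share, 25.9%, was 47.4% with the strongest peaks and 18.3% with fixed windows. The 2 promoter lists became 1 with the longer list, with promoters within 2 kb and with fixed windows (pluripotency and germline lost), 1 with the strongest peaks (mesenchyme and neural crest lost), 0 with promoters within 500 bp and 8 with unmatched lists (pluripotency and germline lost, 7 lists gained). The 10 distal lists became 6 with a window of 200 kb and 5 with unmatched lists (mesenchyme and neural crest, heart, skeletal muscle and mature glia lost with both, early neuron with the latter). They became 9 with the strongest peaks (heart lost), 9 with fixed windows (skeletal muscle lost), 9 with merged peaks (early neuron lost) and 7 with 1 gene per locus (early neuron, skeletal muscle and mature glia lost), and stayed 10 with the longer list, with 50 kb and with shared peaks only. With the starts of all transcripts of protein-coding genes counted as TSSs, 2 promoter lists, 10 distal lists and 35 motifs stayed called, and the promoter share was 26.4%. The 35 motifs between distal and promoter peaks became 23 with whole peaks. GC-matched controls reversed, in mean log2 odds ratio, homeodomain (0.24), LHX (0.19), POU (0.17), TEAD (0.0118) and EBF (-0.0301), and left 22 footprint motifs called, 17 higher and 5 lower (OTX, GATA and TFAP2 among those lost). Whole peaks reversed E-box CAGCTG (-0.20), SRF (-0.0295) and MYB (-0.0801). With 1 replicate left out, the promoter share ranged from 20.8 to 30.9%, promoter lists from 2 to 3, distal lists from 10 to 10, footprint motifs from 33 to 35 and distal-promoter motifs from 37 to 38; each library then stands alone and the requirement of both is dropped. Of 510 counts of shared distal peaks near named genes, 342 stayed within the difference between libraries. Of 522 values of single lists, 492 kept their call status, 8 gained a call and 22 lost it. Of 720 values of single motifs, 645 kept it, 27 gained a call, 40 lost it and 8 reversed. The lists in peaks found in 1 library gave 0 calls under each alternative run, by the rule of the same direction in both libraries.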

Other observations

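The comparison of shared distal peaks with those found in 1 library, the list medians of promoter signal, and the tests below of depth, of lower background and of overlapping peaks were chosen after the results were seen. Shared distal peaks held more matches for CTCF than distal peaks found in 1 library, at odds ratios of 7.93 in replicate 1 and 40.2 in replicate 2, and more for REST, at 4.51 and 95.1, RFX at 6.4 and 5.04, ZIC at 3.97 and 6.88 and SP/KLF at 2.53 and 4.05. They held fewer for GATA, at 0.685 and 0.569, TBR at 0.746 and 0.614 and RUNX at 0.83 and 0.734. Of 48 motifs, 15 were higher and 5 lower in shared peaks in both libraries. The classes were not matched on strength or base composition, so the part of these in the odds ratios was not tested. Median signal was 1.06 in shared distal peaks against 0.405 in the others in replicate 1, and 1.09 against 0.155 in replicate 2. Mean GC was 54.2% against 51.2% and 55.1% against 51.1%. The widest shared hotspot covered the start of Six3, on chromosome 17 at 85611353 to 85627539, with widths of 16187 and 12467 bp. Wide shared hotspots also lay at Cyp26b1, which breaks down retinoic acid (9325 and 11360 bp), Gata2 (13117 and 5634 bp), Ring1, a Polycomb gene (5354 and 12130 bp), and Olig2 (13161 and 3351 bp).

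Promoter signal differed between the replicates by gene group. Over the 14098 genes with a promoter peak in both libraries, the highest promoter signal was higher in replicate 2 by a median of 0.55 on the log2 scale. Of the 16 lists with at least 5 such genes, neural progenitor genes lay above the range of signal-matched lists, with a median of 0.89 against 0.59. Of these 20 genes, 15 rose more than the median of all genes. Sox1 went from 3.63 to 8.69, Pou3f3 from 3.97 to 7.71 and Fabp7 from 2.30 to 3.65. Prom1 rose less than the median of all genes, from 2.85 to 3.54. Posterior Hox genes lay below it, with a median of -0.45 against 0.16, at the percentile of 0 among 10000 lists, as did surface ectoderm and epithelium (-0.40 against -0.02), pluripotency and germline (-0.24 against 0.16) and liver (0.10 against 0.47). The other 11 lists lay within their range, with forebrain patterning at 0.40 against 0.40. With 1 library on each side this describes the libraries and is not a test of a difference.

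Replicate 2 had 1.42 times as many strict peaks as replicate 1. Greater depth is argued against by the ratio of tags behind the normalization, 1.06, if the signal is read as tags per 1 M tags. Repeated sequence is argued against as the main cause. Repeat bases in peaks found in replicate 2 alone exceeded those in its shared peaks by 9.54 percentage points (standard error 0.110). That is below the bound of 10 set beforehand, though the margin is small. The excess was smaller in replicate 1, at 5.01 points (standard error 0.125), so a part played by repeats is left open. A lower background in replicate 2 cannot be told apart from other causes. The signal of the weakest decile of peaks was 1.297 times higher in replicate 1, and that of the next 4 deciles 2.66 to 3.20 times, but deciles of lists of different length shift with the number of peaks, so this decides nothing. No biological explanation was tested because there is 1 group.

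Distal peaks were also dense at regulators of other tissues, such as posterior Hox and heart genes. Windows shared by clustered genes are argued against as the whole cause, since with 1 gene per 200 kb locus both lists stayed past the threshold, at a highest adjusted permutation p of 0.0288. Counting overlapping peaks more than once is argued against too, with a highest adjusted permutation p of 0.0391 after merging, although it raised the counts. CpG-rich sequence could play a part at posterior Hox windows, where the median number of CpG per 100 bp was up to 1.68 times that of all distal peaks, between the bounds set. At heart windows the ratio was at most 1.08. The bound for arguing against this cause had to hold for both lists, and posterior Hox exceeded it. Arguing against it at heart windows alone is a reading by list that the bound did not provide for. No biological explanation was tested, and the heart call ended with a window of 200 kb, with unmatched random lists and with the strongest peaks.

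Homeodomain matches were fewer in footprints than in width-matched controls although the motif was more frequent at distal peaks. With GC-matched controls the odds ratio rose to at most 1.25. Those controls were matched on the GC of the interval itself, and footprints had a median width of 9 bp. A TAATTA match holds no G or C, so this matching can remove a true deficit. Base composition remains a candidate explanation that the GC-matched controls cannot decide. Position within the peak is argued against as the whole cause, since with mirror-image controls the highest odds ratio was 0.589. Whether position plays a part cannot be told from these controls. Their GC stayed lower than that of the footprints, at 57.4% and 56.9% against 65.6% and 63.3%. Only 176863 and 161625 footprints could be used. No biological explanation was tested.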
